A study of Mus musculus with 6 samples.

How the data were processed

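The data are Agilent 1-colour (Cy3) arrays of total RNA from the dorsal forebrain of 6 single mouse embryos, 3 control and 3 mutant. The tissue was dissected on ice and frozen before RNA isolation, per the labels' protocols. The scanner files hold each spot's intensity on a linear scale, which the authors extracted with Agilent Feature Extraction 10.7.3.1 (array design 026655, grid build mm9), per the file headers. The processed signal is background-subtracted within the array and not normalized between arrays, per the file headers. The deposited files also mark, as 0 or 1, spots well above background, saturated spots and outlier spots, per the file headers.

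The authors' deposited table of the whole series gives log2 values of 27269 probes for 3 control and 3 mutant columns, whose medians lie between 9.008 and 9.009, and the step that made them equal is not given in the sources used here. It also holds the authors' log2 ratio, the ratio itself, and a p-value and fdr of mutant against control. The fdr is NA for 15786 probes, all with an absolute log2 ratio of at most 0.2945. The submitters' processing notes name limma without its version or role. The column numbers of that table do not follow the sample titles: set against the arrays, for example, its first mutant column correlates best with the array of mutant 2 (r = 0.904 over deviations from probe means). The columns were therefore used by group only.

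Each array holds 43020 non-control spots for 39429 probes. Outlier spots (non-uniform or population outliers) were left out, spots of a probe were averaged, and log2 of the processed signal was scaled by subtracting its 75th percentile over the non-control spots of the array. Probes well above background on at least 3 of the 6 arrays were kept (26849 probes). Probes without a value on an array (92 in all) were left out. Of several probes of a gene the brightest over the 6 arrays was used, which gave 21067 rows, 17091 of them named genes. Of the 3 changed genes with more than 1 kept probe, 0 had a probe of opposite sign. Probes were named through the accession in a reference table of GRCm38.p6 (26581 probes), used for names only, or else by the symbol in the authors' table (2038 found in the reference and 1082 kept as given), and 9728 stayed unnamed. Probe positions are those the authors' table gives for the array.

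Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a variance trend, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures. Of 33 gene lists written before the data were examined, 32 had at least 4 measured genes and were tested with limma's camera at a preset inter-gene correlation of 0.01. The list of sex-linked genes had fewer. Xist was well above background on all 6 arrays, and of the Y-linked probes only that of Zfy1 on control 3 was. The lists of 8 kinds of genes lead the text: Wnt targets, cortical hem, medial pallium, radial glia, basal progenitors, neurons, Cajal-Retzius cells and astroglia. The samples are separate embryos, per the labels.

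Genes are named by a rule written before the data were examined: Ctnnb1, Axin2 and Lef1; the 12 largest rises and 12 largest falls past the threshold whose groups do not overlap, with genes of smallest unadjusted p added up to 6 where under 3 pass in a direction, clone names skipped; and up to 4 genes of each list with the smallest p. A gene named outside the rule, including list members of higher p named to complete a count, was chosen after its values were seen.

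The titles give the litter that a control and a mutant share, so that litters pair the samples. Deviations from the group means correlated at 0.308, 0.357 and 0.107 within litters 1, 2 and 3, and from -0.41 to 0.109 between litters. The fit with litter as a block is given for the genes changed over all rows and for each list whose call it changes. It was not made for genes adjusted over a list alone, so whether it would change those calls was not tested. Slide (2 slides, scanned apart) was also used as a block.

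The alternatives were normexp background correction (offset 50), quantile normalization, median centring, no filter and a filter on all 6 arrays, all probes, the mean of a gene's probes, litter or slide as a block, trend with robust variance, array weights, an adjusted p under 0.1, a log2 difference of at least 1, omission of sex-linked genes, the authors' log2 values, an estimated correlation or fry for lists, lists without shared genes, and omission of each embryo in turn. Normexp used the median signal with the median background, since the mean signal was not used here. Added after seeing the data were the litter block with trend and robust variance, omission of litter 3, slide 2 alone, a variance trend in camera, an estimated correlation with each embryo left out in turn, and omission of probes that share one profile.

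The fit was tested on simulated arrays of the same 21067 rows, with the means and spreads of the real ones and 200 genes changed. It recovered 26%, 54%, 86% and 100% of genes changed by 0.5, 1, 2 and 3 on the log2 scale (50 genes each), and called 8 unchanged genes. A simulated shift of 1 list was found, with 0 of the other lists called. The simulated genes varied independently and without litter effects, unlike the real ones. The correlation estimated in the real lists was, for example, 0.658 for neurons and 0.826 for erythroid genes. The simulation therefore cannot show how often the list test calls unchanged lists on these arrays. Gene ontology terms came from identifiers in the authors' table, 571 terms with 15 to 300 tested genes over 5896 genes, and the terms' names were supplied from general knowledge of the ontology. Their test was exploratory.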

Results

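Gene expression was measured in the dorsal forebrain of single mouse embryos at E11.5, on 1-colour arrays, for 3 control and 3 mutant embryos. The labels call the groups control and mutant without naming the mutated gene, and the series title places the comparison within Wnt/beta-catenin signalling and the successive fates taken by precursors of the cortex. Control 1 and mutant 1 came from one litter, as did control 2 and mutant 2, and control 3 and mutant 3. The share of spots well above background was 70.1%, 69.89% and 68.68% on the arrays of controls 1, 2 and 3, and 65.75%, 67.78% and 67.9% on those of mutants 1, 2 and 3. The 75th percentile of the processed signal was 1833.2, 1480.0 and 1446.2 in controls 1, 2 and 3, and lower in each of mutants 1, 2 and 3 (1318.8, 1380.2 and 1206.9). No spot was saturated. Each array is scaled by this value, which can set signals near background higher in the mutants. The probe of Ddx3y, above background on no array, was at -9.27, -9.28 and -9.24 in the controls and at -8.45, -8.70 and -8.96 in the mutants. Control 1 and mutant 1 shared slide 1, and the other 4 arrays shared slide 2. Levels are log2 signals relative to the 75th percentile of the same array, differences are mutant minus control with their standard error (SE), and the number of arrays, 3 in each group, limits the precision of every value.

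Ctnnb1, which encodes beta-catenin, the coactivator of canonical Wnt signalling and a component of adherens junctions, was measured at 3.80, 3.86 and 3.79 in controls 1 to 3 and at 3.39, 3.68 and 3.54 in mutants 1 to 3. The log2 difference of -0.275 (SE 0.09) did not pass the test over all genes (limma, adjusted p = 0.243). The single Ctnnb1 probe lies on chromosome 9, from 120869274 to 120869333 in the mm9 annotation of the array, and if the mutated part of a gene lies outside the probe, its level checks nothing about the labels.

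The list of Wnt/beta-catenin target genes, fixed before the data were examined, shifted lower in the mutants (26 genes, 17 of them with negative differences, mean log2 difference -0.47, median -0.08, limma camera, adjusted p = 0.0031, and 0.623 with an estimated correlation). The list median from the control mean was -0.174, -0.013 and -0.382 in mutants 1, 2 and 3, against -0.077, 0.016 and 0.042 in controls 1, 2 and 3. That of mutant 2 thus lay within the control range. Adjusted over the list alone, 10 of the 26 genes were lower and 4 were higher. In limma over all genes 0 of them passed, with 14 at an unadjusted p under 0.05, against 3569 of all 21067 rows. The 10 included Lef1, a DNA-binding partner of beta-catenin (2.95 ± 0.16 in controls and 1.88 ± 0.19 in mutants, SD, n = 3 each), Axin2, a feedback inhibitor of the pathway (-1.33 ± 0.30 and -1.93 ± 0.21), Tnfrsf19, a receptor of the tumour necrosis factor family (log2 difference -1.36, SE 0.12), and Trabd2b, a metalloprotease that inactivates Wnt proteins (-0.91, SE 0.09). Among the others were Sp5, a zinc-finger transcription factor (-4.09, SE 0.86), and the secreted Wnt inhibitor Wif1 (-3.44, SE 0.53), both chosen after their values were seen, with Sp5 above background on 2 of the 3 mutant arrays. With normexp background correction these differences were -2.57 for Sp5 and -2.08 for Wif1, and that of Sp5 was -4.74 without mutant 1 and -3.08 without mutant 3. The fdr in the authors' deposited table, from the same arrays, was 0.0253 for Lef1, 0.0246 for Sp5, 0.0249 for Wif1 and 0.0781 for Axin2. The 4 higher genes were Kremen1 (0.45), Neurog1 (0.51), Id2 (0.25) and Zcchc12 (0.74), of which Neurog1 is a proneural factor and Id2 an inhibitor of such factors. Litter as a block left the list past the threshold (adjusted p = 0.0279), as did leaving out each embryo in turn, with medians of -0.228, -0.195 and -0.024 without mutants 1, 2 and 3. The median differences were -0.15 within slide 1 and -0.22 within slide 2. Wnt ligands, receptors and modulators did not shift as a list (27 genes, median 0.07, adjusted p = 0.915). Adjusted over the list alone, the receptors Fzd1 (-0.82), Fzd9 (-0.95) and Fzd7 (-0.37) were lower, and Wnt7a (0.67), Fzd8 (0.53) and Fzd5 (0.56) were higher. With the mean of a gene's probes Fzd5 was at 0.26 and Fzd7 at -0.17.

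Over all 21067 genes and unnamed probes tested, 7 genes changed, 2 of them higher and 5 lower in the mutants, while 0 passed with litter as a block. Prr15 fell 7.6-fold, from 0.88 ± 0.19 to -2.05 ± 0.26 (SD, n = 3 each, limma, adjusted p = 0.02). Plpp4, a phospholipid phosphatase, fell 3.34-fold (log2 difference -1.74, SE 0.09), and Chst2, a carbohydrate sulfotransferase, fell 3.09-fold (-1.63, SE 0.12). Flrt3, a transmembrane adhesion protein, fell 2.86-fold, and the orphan nuclear receptor Rora fell 2.19-fold. Prdm12, a PR-domain transcriptional regulator known from sensory neurons, rose 2.4-fold (-0.20 ± 0.06 to 1.07 ± 0.06, adjusted p = 0.02). The clone-named gene E030018B13Rik, chosen after its values were seen, rose by 1.88 on the log2 scale (SE 0.14), but was above background on only 1 of the 3 control arrays, so that this size is uncertain. The sizes of 3 of the 7 depended on the processing, of which normexp changed both the background correction and the signal used. With normexp background correction the log2 difference was -0.715 for Plpp4, -0.701 for Rora and 0.692 for E030018B13Rik. The log2 ratio in the authors' deposited table was -1.35 for Plpp4, -1.04 for Rora and 0.733 for E030018B13Rik. All 3 mutant values lay on the same side of the control range for each of the 7, and so did those of 24.9% of all tested genes, against 10% by chance. The probes lie in mm9 on chromosome 6 from 54280124 to 54280183 (Prr15), chromosome 7 from 136534383 to 136534442 (Plpp4), chromosome 9 from 95304932 to 95304991 (Chst2) and from 69226774 to 69226833 (Rora), and chromosome 2 from 140485061 to 140485120 (Flrt3) and from 31511125 to 31511184 (Prdm12), and that of E030018B13Rik on chromosome 7 from 71065149 to 71065208.

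The genes that came next stayed short of the threshold. On the higher side, by the naming rule, these were Fabp7, the brain lipid-binding protein of radial glia (log2 difference 1.39, SE 0.13), Vldlr, a receptor for reelin (1.05, SE 0.09), Pdlim3 (1.66), Rergl (1.49) and Asrgl1 (0.88), each at an adjusted p of 0.0546. With normexp background correction the differences were 0.955 for Pdlim3 and 0.658 for Rergl, and the authors' log2 values gave 1.07, 0.725 and 0.54 for Pdlim3, Rergl and Asrgl1. The fdr of Fabp7 in the authors' deposited table was 0.0127. Sult1e1, a sulfotransferase chosen after its values were seen, was not well above background in any mutant and at least 3.68-fold lower than in controls (adjusted p = 0.0516). This bound depends on the processing, since the log2 difference of Sult1e1 was -2.53, but -0.295 with normexp and -0.96 with the authors' log2 values. Such a bound sets the control mean against the mean, per mutant array, of the higher of the gene's own signal and the lowest signal well above background. The Wnt receptor Ror2 (-1.46, SE 0.12, adjusted p = 0.0546) and the proto-oncogene Mycn (-1.21, SE 0.12, adjusted p = 0.0593), also chosen after their values were seen, had negative differences that did not pass.

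With litter as a block, 0 genes passed in limma (smallest adjusted p = 0.156, with 4181 genes at an unadjusted p under 0.05 against 3569 without the block). With slide as a block 0 genes passed (smallest adjusted p = 0.0688, 4149 at an unadjusted p under 0.05). On slide 2 alone 0 passed as well (3847 at an unadjusted p under 0.05), while slide 1, with 1 embryo of each group, allows no test. The differences of Prr15 were -3.20 within slide 1 and -2.79 within slide 2, and those of Prdm12 were 1.25 and 1.27. Leaving out any single embryo left 0 of the 7 past the threshold, and 1 other gene passed without mutant 1. The counts at an unadjusted p under 0.05 were then 2927, 2629 and 1914 without controls 1, 2 and 3, and 4515, 2736 and 3122 without mutants 1, 2 and 3. With normexp background correction, 149 genes passed, 51.7% of them higher, against 28.6% of the 7. With a variance trend and robust variance, 143 passed, and both sets held all 7. In the authors' deposited table all 7 probes have an fdr under 0.05, from 0.00361 to 0.0244, among 357 such probes (109 higher and 248 lower). That table comes from the same 6 arrays and is no independent support. Its fdr is NA for 15786 probes, so it may not be adjusted over the same rows as here.

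**Figure D1:**
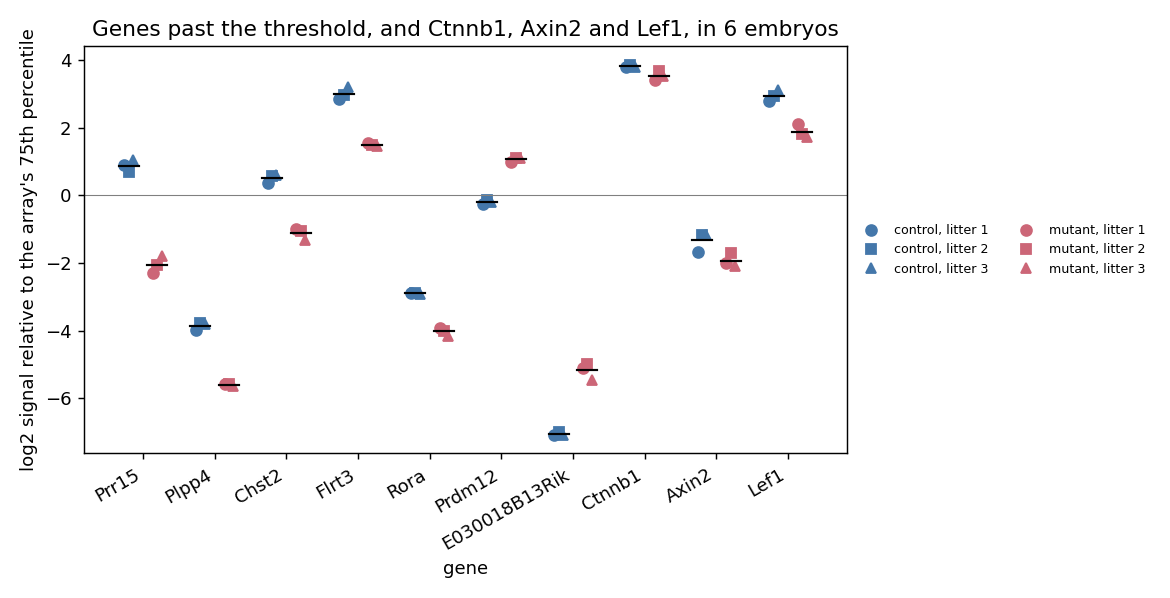
Log2 signal relative to the 75th percentile of the array (vertical axis) for the 7 changed genes and for Ctnnb1, Axin2 and Lef1 (horizontal axis), with 1 point per embryo, colours for the groups, marker shapes for the litters and black lines for the group means. In each of these 10 genes the 3 mutants lie outside the range of the 3 controls, and Prr15 falls from 0.88 to -2.05 on average.

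Genes that pattern the medial pallium and hippocampal primordium moved both ways. Of 18 genes, 6 were lower and 3 were higher when adjusted over the list alone. The lower genes were the homeobox genes Emx2 (-0.93, SE 0.10), Lhx2 (-0.58, SE 0.09) and Emx1 (-0.81, SE 0.25), the doublesex-related genes Dmrt3 (-1.24, SE 0.17) and Dmrta2 (-0.50, SE 0.09), and Lef1. The higher genes were the nuclear receptor Nr2f2 (0.78, SE 0.10), Zbtb20 (0.77, SE 0.18) and Prox1 (0.71, SE 0.23), the latter a homeobox gene of the dentate gyrus. Prox1 was at 0.39 with normexp and at 0.27 with the authors' log2 values. As a list they did not shift (median 0.03, mean -0.08, test towards lower, limma camera, adjusted p = 0.202). The list of the antihem and lateral pallium did not pass (8 genes, median 0.29, adjusted p = 0.071), except with median centring (0.0423) or without genes of several lists (0.0187). Its median was 0.17 without control 3, 0.06 within slide 1 and 0.51 within slide 2. There Dbx1, a homeobox gene of the ventral pallium (1.22, SE 0.18), and Fezf1 (0.62) were higher and Emx1 was lower, adjusted over the list alone.

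Genes of the cortical hem, the Wnt- and Bmp-secreting margin of the medial pallium, differed among the mutants. The median difference of the 13 hem genes from the control mean was 1.40, 0.67 and -0.70 in mutants 1, 2 and 3, against -0.14, -0.12 and 0.28 in controls 1, 2 and 3. The list of the meninges and head mesenchyme was likewise highest in mutant 1 and lowest in mutant 3 (0.83, -0.22 and -0.65). Rspo2, a secreted enhancer of Wnt signalling, was at 0.21, -0.13 and -6.88 in mutants 1, 2 and 3 and at -7.59, -7.62 and -5.33 in the controls. Bmp6 was at -3.12, -3.34 and -6.55 in the mutants and at -7.73, -7.58 and -6.34 in the controls. Rspo2 and Bmp6 were each above background on 1 of the 3 control arrays, and their differences of 4.58 and 2.88 were 2.99 and 1.34 with normexp. Wnt8b was at 0.48, -0.12 and -6.15 in the mutants and between 0.54 and 1.35 in the controls. The list did not shift (median 0.39, adjusted p = 0.557, with 1.08 within slide 1 and 0.06 within slide 2), but it did without mutant 3 (median 1.06, adjusted p = 0.000724). This call was lost with an estimated correlation (adjusted p = 0.366). The median was 0.26 without control 3 (adjusted p = 0.534), -0.08 without mutant 1 (0.524) and 0.28 without mutant 2 (0.922). Choroid plexus genes had a median of 0.93 (10 genes, adjusted p = 0.134), 1.28 without mutant 3 (adjusted p = 0.00152, and 0.366 with an estimated correlation) and 0.53 without mutant 1 (0.566). Among them Clic6 (1.54, SE 0.76) was at -2.53, -1.97 and -4.83 in mutants 1, 2 and 3 and at -5.00, -4.18 and -4.79 in the controls. The Bmp pathway list, which shares genes with the hem list, had a median of 0.19 (adjusted p = 0.238). It was 0.44 without mutant 3 (adjusted p = 0.0051, and 0.366 with an estimated correlation), 0.04 without mutant 1 (0.786) and 0.095 without control 3 (0.262).

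**Figure D2:**
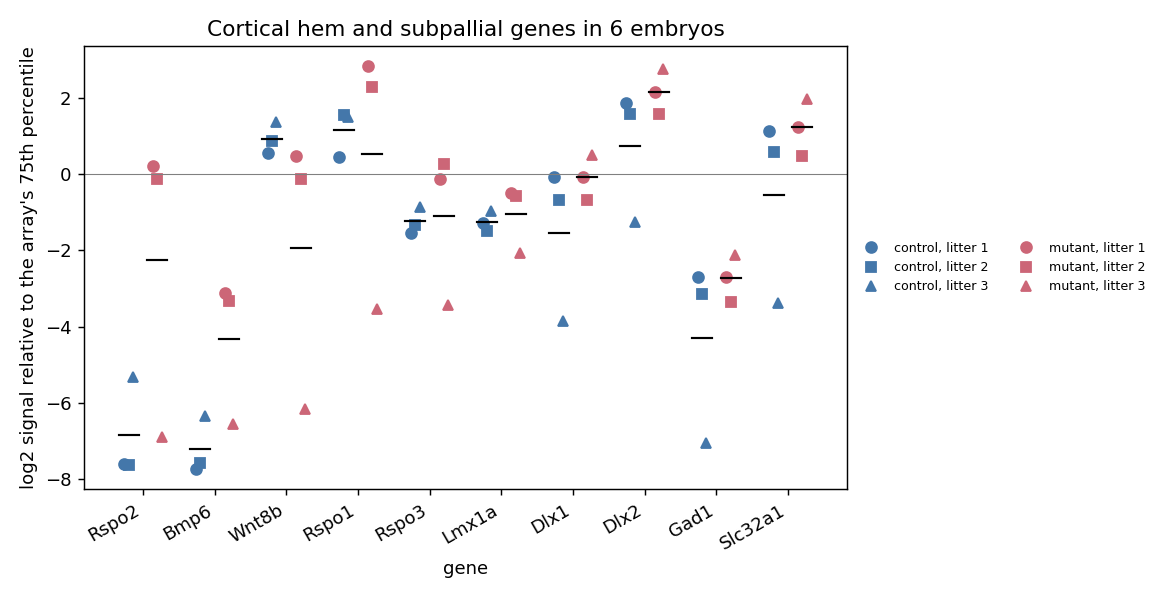
Log2 signal relative to the 75th percentile of the array (vertical axis) for 6 cortical hem and 4 subpallial genes (horizontal axis), with 1 point per embryo, colours for the groups, marker shapes for the litters and black lines for the group means. Mutant 3 lies below the other mutants for the hem genes (Rspo2 at -6.88 against 0.21 and -0.13), and control 3 lies below the other controls for the subpallial genes.

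Neuronal genes shifted higher in the mutants. Of 28 genes of post-mitotic neurons, 27 had positive differences (median 0.37, limma camera, adjusted p = 3.41e-05, and 0.623 with an estimated correlation), among them the cell adhesion molecule Ncam1 (0.50, SE 0.14), the growth cone protein Gap43 (0.61, SE 0.17), Myt1 (0.55, SE 0.16) and Celf4 (0.55, SE 0.20), although 0 genes passed in limma over all genes or adjusted over the list alone (9 at an unadjusted p under 0.05). Genes of basal progenitors and neurogenic commitment also shifted higher (22 genes, 20 of them positive, median 0.24, adjusted p = 0.00184, and 0.623 with an estimated correlation). Rasgef1b (0.48, SE 0.09), the zinc-finger factor Insm1 (0.69, SE 0.14) and the Notch ligand Dll3 (0.42, SE 0.10) were higher adjusted over the list alone. The list median from the control mean was 0.00, 0.43 and 0.39 in mutants 1, 2 and 3 for basal progenitors and 0.08, 0.45 and 0.63 for neurons. Within slide 1, which holds mutant 1, the median differences were -0.005 and -0.06, against 0.39 and 0.61 within slide 2. Litter as a block left both lists past the threshold (adjusted p = 0.00854 and 0.000889). Without mutant 1 the medians were 0.37 and 0.55, and without mutant 3 that of neurons was 0.23. The absence of a filter on dim probes ended the call of basal progenitors (adjusted p = 0.0891). Mutant 1, the lowest of the mutants in both lists, was the highest of them in several lists of other cells or regions. The list median in mutants 1, 2 and 3 was 0.83, -0.22 and -0.65 for the meninges and head mesenchyme, 0.24, 0.005 and -0.31 for the endothelium, and 0.12, -0.35 and -0.44 for microglia and macrophages. In controls 1, 2 and 3 these medians were 0.08, 0.07 and -0.26, then -0.12, 0.12 and 0.01, and 0.13, 0.075 and -0.18. Mutant 1 was also highest of the mutants for the choroid plexus, cortical hem, diencephalon, eye field and, by little, surface ectoderm (0.111 against 0.104 in mutant 2). It was not for erythroid (-0.13, -0.10 and -0.99) or subpallial genes (1.32, 0.81 and 1.70). For the antihem and lateral pallium it was the lowest of the mutants (0.104, 0.255 and 0.441).

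Genes later used as markers of upper cortical layers shifted higher (15 genes, median 0.49, adjusted p = 0.00184, 0.012 with litter as a block and 0.488 with an estimated correlation). Their median was 0.26 within slide 1 and 0.54 within slide 2, and the absence of a filter on dim probes ended the call (adjusted p = 0.0773). Adjusted over the list alone, 8 of them were higher, including the adhesion molecule Nectin3 (0.52, SE 0.09), the ephrin receptor Epha3 (0.76, SE 0.17), Lmo4 (0.42, SE 0.10) and the POU-domain factor Pou3f3 (0.49, SE 0.12). Genes of deep layers and the preplate did not shift (20 genes, median 0.21, adjusted p = 0.305). The median was 0.29 without mutant 1 (adjusted p = 0.0257, and 0.435 with an estimated correlation) but 0.03 without mutant 2 (0.918), and -0.06 within slide 1 against 0.36 within slide 2 (0.0461). There Ntng1 was higher (1.12, SE 0.16) and Fezf2, a determinant of subcerebral projection neurons, was lower (-0.81, SE 0.13), adjusted over the list alone. Genes of Cajal-Retzius cells, the early reelin-producing neurons, had a median of 0.25 (16 genes, 14 of them positive, adjusted p = 0.071). Reln itself, chosen after its values were seen, was at 0.25 (SE 0.20), and from 0.089 to 0.514 over the other settings. The Cajal-Retzius list passed without control 2 (adjusted p = 0.0232) or mutant 3 (median 0.37, 0.00864), though not with an estimated correlation (0.667 and 0.431), and its median was 0.16 without mutant 2 (0.525).

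Genes of radial glia and of astroglia did not pass as lists. For radial glia the median was 0.16 (21 genes, adjusted p = 0.0889). It was 0.27 without mutant 1 (adjusted p = 0.0432, and 0.495 with an estimated correlation) and 0.07 without mutant 3 (0.229). Adjusted over the list alone 5 of them were higher, among them Fabp7, the glutamate transporter Slc1a3 (0.99, SE 0.18), the endothelin receptor Ednrb (1.09, SE 0.22) and Ddah1 (0.73, SE 0.16), and the chromatin protein Hmga2 was lower (-0.36, SE 0.08, and -0.15 with the mean of its probes). For astroglia the median was 0.39 (20 genes, adjusted p = 0.0694). The list passed without control 3 (adjusted p = 0.0499) or mutant 3 (0.0353), though not with an estimated correlation (0.619 and 0.366). There Ptprz1 (0.69, SE 0.11), Slc1a3, Acsbg1 (0.72, SE 0.16) and Aqp4 (0.56, SE 0.14, and 0.25 with the authors' log2 values) were higher and the nuclear factor I genes Nfix (-1.74, SE 0.15) and Nfib (-0.66, SE 0.18) were lower, adjusted over the list alone. Quantile normalization, which moved both lists past the threshold, gave adjusted p of 0.0085 for radial glia and 0.0208 for astroglia.

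**Figure D3:**
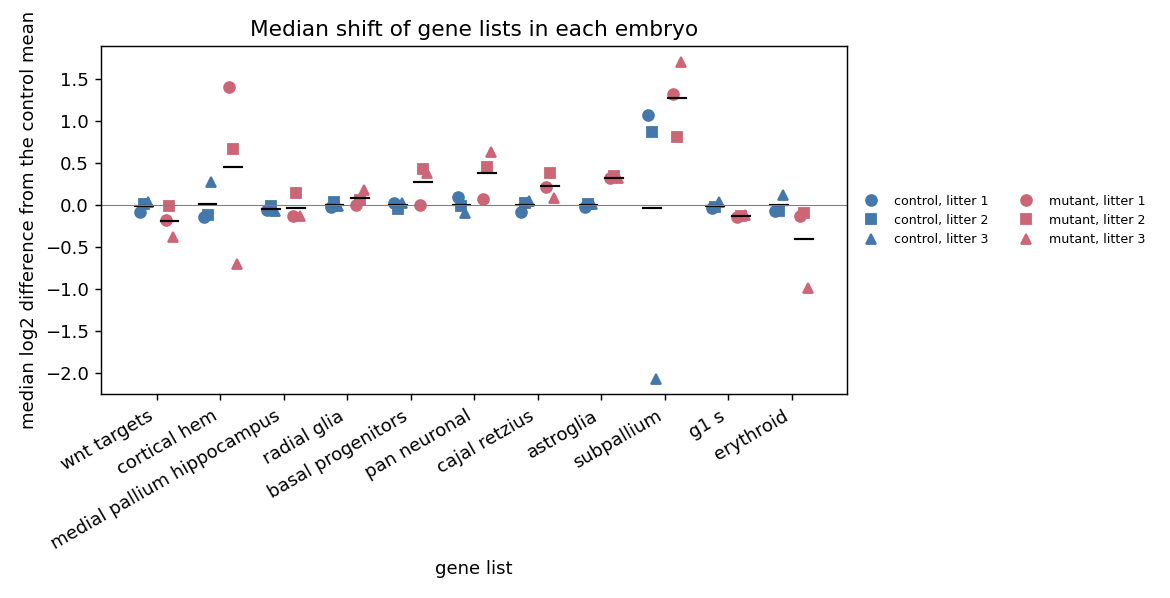
Median log2 difference from the control mean over the genes of a list (vertical axis) for the 8 leading lists and for subpallial, G1 and S phase and erythroid genes (horizontal axis), with 1 point per embryo, colours for the groups, marker shapes for the litters and black lines for the group means. The 3 mutants lie together for astroglia (0.32, 0.34 and 0.32) and spread from -0.70 to 1.40 for the cortical hem.

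Genes of G1 and S phase shifted slightly lower in the mutants (27 genes, 25 of them negative, median -0.12, limma camera, adjusted p = 0.000153, and 0.488 with an estimated correlation), with medians of -0.14, -0.13 and -0.11 in mutants 1, 2 and 3. The median was -0.09 within slide 1 and -0.12 within slide 2. Examples were the cyclin Ccne1 (-0.40, SE 0.10), the replication helicase subunits Mcm7 (-0.21) and Mcm5 (-0.22) and the transcription factor E2f2 (-0.27). In limma 0 of the 27 passed adjusted over the list alone, with 5 at an unadjusted p under 0.05, against 3569 of all 21067 rows. Genes of G2 phase and mitosis had a median of -0.03 (26 genes, adjusted p = 0.0269, 0.626 with an estimated correlation), and did not pass without control 3 (0.0956), without mutant 1 (median -0.02, 0.184), with quantile normalization (0.133) or with the authors' log2 values (0.119). The median was -0.08 without mutant 3 (0.0031), -0.06 without control 1 or 2 and -0.05 without mutant 2. It was -0.11 within slide 1 and -0.02 within slide 2 (0.107). The list of inhibitors of cyclin-dependent kinases shifted higher, with positive differences in 6 of 6 genes (median 0.21, adjusted p = 0.0414, 0.488 with an estimated correlation). In limma 0 of them passed over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05). Cdkn1c was at 0.57 (SE 0.21), and from 0.374 to 0.691 over the other settings. The list did not pass without control 1 (0.105) or mutant 2 (0.104), with normexp (0.169), without the filter on dim probes (0.32) or without genes of several lists (0.0685). Without mutant 1 the median was 0.33. Their median was 0.18 within slide 1 and 0.30 within slide 2 (0.0585).

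Genes of the FGF pathway shifted higher (18 genes, median 0.17, adjusted p = 0.0444, 0.623 with an estimated correlation). Adjusted over the list alone the ETS factors Etv1 (0.80, SE 0.12) and Etv5 (1.02, SE 0.19), the receptor Fgfr1 (0.32, SE 0.06) and the feedback inhibitor Spry2 (0.76, SE 0.16) were higher, while Sp8 (-0.74, SE 0.09) was lower. With the mean of a gene's probes Fgfr1 was at 0.19 and Sp8 at -0.36, and with the authors' log2 values Spry2 was at 0.498. The list did not pass without control 1 (adjusted p = 0.115), control 3 (0.0523), mutant 1 (0.0928) or mutant 2 (0.14), nor with normexp (0.176), without the filter on dim probes (0.513) or with array weights (0.0748). Without control 2 the median was 0.27. Its median was 0.32 within slide 1 and 0.24 within slide 2 (0.122). Adherens junction genes also shifted higher (20 genes, median 0.15, adjusted p = 0.0433, 0.488 with an estimated correlation), with the cadherin Cdh6 (0.64, SE 0.09) and Nectin3 higher adjusted over the list alone. Litter as a block ended that call (adjusted p = 0.0964), as did leaving out control 1 (0.105), control 2 (0.088), mutant 1 (0.0578) or mutant 3 (0.054). It also ended with normexp (0.137), without the filter on dim probes (0.32) and without genes of several lists (0.107). Its median was 0.08 within slide 1 and 0.15 within slide 2 (0.0968). The Notch list (23 genes, median 0.002, mean 0.01, test towards lower, adjusted p = 0.943), the Sonic hedgehog list (11 genes, median -0.02, adjusted p = 0.187) and the p53 and apoptosis list (19 genes, median 0.12, adjusted p = 0.305) did not shift. Of these, Gas1, a membrane protein that binds hedgehog, was lower adjusted over its list alone (-0.71, SE 0.12). When single embryos were left out, the medians ran from -0.093 to -0.001 for Sonic hedgehog and from 0.069 to 0.147 for p53 and apoptosis.

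Markers of other cells that a dissected dorsal forebrain can hold also differed. Subpallial genes shifted higher in the mutants (20 genes, median 1.32, adjusted p = 0.0269, 0.684 with an estimated correlation), but control 3 was low in them: the list medians were 1.08, 0.87 and -2.06 in controls 1, 2 and 3 and 1.32, 0.81 and 1.70 in the mutants. Dlx1, a homeobox gene of the subpallium, was at -0.09, -0.68 and -3.86 in controls 1, 2 and 3. The call was lost with litter as a block (adjusted p = 0.0641), without control 3 (median 0.26, adjusted p = 0.302), without mutant 1 (0.114) and without mutant 3 (0.108). It was also lost with normexp (0.0908), without the filter on dim probes (0.224), with array weights (0.0681) and without the probes of one shared profile (0.0611), an omission chosen after seeing the data. The median was 0.05 within slide 1 and 1.81 within slide 2. Erythroid genes shifted lower, negative in 16 of 16 (median -0.36, adjusted p = 0.00214, 0.626 with an estimated correlation), with medians of -0.13, -0.10 and -0.99 in mutants 1, 2 and 3, and did not pass without mutant 3 (median -0.09, adjusted p = 0.115). Their median was -0.05 within slide 1 and -0.53 within slide 2. Microglial and macrophage genes shifted lower (16 genes, 14 of them negative, median -0.23, adjusted p = 0.0414, 0.626 with an estimated correlation), but not without control 1 (0.115), control 2 (0.122), mutant 2 (0.168) or mutant 3 (0.163). The call was also lost with normexp (median -0.07, 0.373), median centring (0.0508), the mean of probes (0.0533) and, chosen after seeing the data, a variance trend in camera (0.0513), and without mutant 1 the median was -0.45. Their median was 0.06 within slide 1 and -0.43 within slide 2. Adjusted over each list alone, 0 subpallial, erythroid or microglial genes passed in limma (2, 3 and 1 at an unadjusted p under 0.05, against 3569 of all 21067 rows). The 1 microglial gene, Itgam, went against its list, with differences of 1.18 within slide 1 and 1.09 within slide 2. Its probe is among those of one shared profile, as is that of Lhx6, 1 of the 2 subpallial genes. Without these probes the difference of Lhx6 was -0.226.

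The remaining lists did not pass at the settings used throughout. Genes of the meninges and head mesenchyme (22 genes, median 0.03, test towards lower, adjusted p = 0.54) and of the endothelium (18 genes, median -0.08, adjusted p = 0.305) were lower past the threshold only without mutant 1 (medians -0.38 and -0.19, adjusted p = 9.1e-05 and 0.00415, and 0.495 and 0.634 with an estimated correlation) and within slide 2 (-0.35 and -0.24). The medians were 0.19 for the diencephalon (17 genes, adjusted p = 0.362), 0.08 for the surface ectoderm (12 genes, adjusted p = 0.626) and -0.07 for the eye field (10 genes, adjusted p = 0.0973). The diencephalon list passed with normexp (adjusted p = 0.0313) and with probes above background on all 6 arrays (0.0341). The eye field list passed in the latter setting (median -0.58, adjusted p = 0.00574) and without mutant 1 (median -0.37, adjusted p = 0.0432, and 0.435 with an estimated correlation). Immediate early and stress genes had a median of -0.05 (17 genes, adjusted p = 0.373), and hypoxia-responsive and glycolytic genes of 0.12 (19 genes, adjusted p = 0.187). The latter passed without mutant 3 (median 0.19, adjusted p = 0.0051, and 0.431 with an estimated correlation), and their median was 0.03 without mutant 1 (0.649) and 0.04 without control 1 (0.607). In all, 12 of 32 lists passed with the preset correlation and 0 with an estimated one in limma camera, where 2 lists had an unadjusted p under 0.05, and fry, a self-contained test, called 3 (upper layer, G1 and S phase, and adherens junction genes, adjusted p = 0.0337 each). With slide as a block 12 of the 12 lists stayed past the threshold (adjusted p from 0.000145 to 0.0497), and within slide 2 alone 8 did.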

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

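The litter block with trend and robust variance, the omission of litter 3, slide 2 alone, the variance trend in camera, the estimated correlation with 1 embryo left out and the omission of probes with one shared profile were chosen after seeing the data, and all other settings before. Ctnnb1 kept its direction and stayed short of the threshold under every setting, from -0.347 to -0.202 when single embryos were left out. Over all settings 3468 of 3669 values of named genes and 702 of 927 list values kept their direction and side of the threshold. Another 16 gene and 45 list values reversed, none of them past the threshold. Most named genes never passed, and staying short counts as kept, so these shares do not show that calls held. The 7 changed genes passed in 8 of 22 (E030018B13Rik) to 12 of 23 (Prr15) other settings. The 12 called lists passed in 12 of 29 (subpallial genes) to 22 of 29 (G1 and S phase). For the values below the cause was not tested, except that leaving out embryos or adding a block leaves fewer degrees of freedom. Signal over background limits the dim genes: 65.75% to 70.1% of the spots of an array were well above background, and without the filter on dim probes the median difference of all genes was 0.109.

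The count of 7 changed genes (2 higher, 5 lower) became 149 (77 and 72) with normexp, 15 (4 and 11) with quantile normalization, 26 (10 and 16) with probes above background on all 6 arrays, 143 (56 and 87) with trend and robust variance, 19 (6 and 13) with array weights, 80 (34 and 46) at an adjusted p under 0.1 and 22 (5 and 17) with the authors' log2 values. It fell to 2 (0 and 2) with the mean of a gene's probes, to 2 (1 and 1) with the litter block, trend and robust variance, and to 1 (1 and 0) without litter 3. It was 0 (0 and 0) in limma without the filter, where 7916 rows had an unadjusted p under 0.05, and 0 (0 and 0) with litter as a block (4181 such rows), with slide as a block (4149) and on slide 2 alone (3847). Leaving out single embryos gave 0 to 1 changed genes, 0 to 0 higher and 0 to 1 lower. The 7 genes were shared with normexp, quantile normalization, median centring (10 genes), trend and robust variance and array weights, and 6 of them with the filter on all 6 arrays and the authors' values.

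The count of 12 lists became 8 with normexp, 7 without the filter, 10 with array weights, 11 without genes of several lists, on slide 2 alone, with the variance trend in camera and without the probes of one shared profile, 3 with fry and 18 without litter 3. It was 14 with quantile normalization, median centring, the filter on all 6 arrays and the authors' values. It was 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05 in limma. Leaving out single embryos gave 8 to 14, and 0 with an estimated correlation (smallest adjusted p = 0.35, with 0 to 2 lists at an unadjusted p under 0.05). Normexp ended the calls of the subpallial, FGF, cyclin-dependent kinase inhibitor, adherens junction and microglial lists. The absence of a filter ended the first 4 of these and those of basal progenitors and upper layers. Array weights ended the calls of the subpallial and FGF lists. The litter block ended the calls of subpallial and adherens junction genes and changed no other list call. With an estimated correlation and with fry, the medians are those of the main setting (Wnt targets -0.078, basal progenitors 0.236, neurons 0.368), at adjusted p of 0.623 for each with the former and 0.0767, 0.21 and 0.224 with the latter. Quantile normalization brought radial glia (0.172), Cajal-Retzius cells (0.219) and astroglia (0.362) past the threshold, as did the authors' values (0.18, 0.206 and 0.276). Median centring did so for Cajal-Retzius cells (0.205) and astroglia (0.352), the mean of probes for Cajal-Retzius cells (0.27), and the absence of a filter for the medial pallium (0.031), where it ended the call of basal progenitors (0.236, adjusted p = 0.0891). Without litter 3 the cortical hem (0.853, adjusted p = 1.68e-06), Cajal-Retzius cells (0.286) and astroglia (0.292) passed, as did the lists of the choroid plexus, Bmp, hypoxia, Wnt ligands and surface ectoderm. When single embryos were left out the medians ran from -0.228 to -0.024 for Wnt targets, -0.075 to 1.056 for the hem, -0.019 to 0.111 for the medial pallium, 0.066 to 0.272 for radial glia, 0.179 to 0.365 for basal progenitors, 0.225 to 0.553 for neurons, 0.156 to 0.37 for Cajal-Retzius cells and 0.315 to 0.417 for astroglia.

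Values that reversed were, with normexp, Pax7 (0.078, not well above background in any mutant), Gbx2 (0.014), Cd68 (0.103), Ptprc (0.105), Egr2 (0.213) and the Wnt ligand list (0.036). With quantile normalization, array weights, the authors' values, the mean of probes and fry, the Notch list reversed (0.022, 0.047, 0.037, 0.032 and 0.002), and with the mean of probes also Smo (0.413). Without the filter the lists of Wnt ligands (0.136), deep layers (0.19) and surface ectoderm (-0.028) reversed, and with all 6 arrays above background those of Wnt ligands (0.038) and the cortical hem (0.197). Without genes of several lists the Wnt ligands (-0.025) and medial pallium (0.273) reversed. Without litter 3 the reversed values were Rspo1 (1.555), Dlx1 (-0.005), Gad1 (-0.122) and the lists of the subpallium (-0.009), Notch (0.014), meninges (0.22), endothelium (0.096) and immediate early genes (-0.027). On slide 2 alone they were Rspo3 (-0.495) and the lists of Wnt ligands (0.014), cortical hem (0.063), diencephalon (-0.014), surface ectoderm (-0.054) and hypoxia (0.008). Without the probes of one shared profile Lhx6 reversed (-0.226). A list's direction here is that of its test, which can differ from the sign of its median. When single embryos were left out the reversing results ran from -0.075 to 1.056 (cortical hem, reversed at -0.075 without mutant 1 and 0.275 without mutant 2), -0.544 to 1.299 (Rspo3), -1.791 to 1.383 (Rspo1), -0.078 to 0.851 (Pdgfra), -0.08 to 0.094 (Wnt ligands), 0.004 to 0.031 (Notch), 0.129 to 0.212 (diencephalon), -0.059 to 0.197 (surface ectoderm), -0.379 to 0.347 (meninges) and -0.185 to 0.093 (endothelium).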

Other observations

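The tests of control 3, of mutant 3, of the splits for changed genes and for lists, and the gene ontology test itself were chosen after the results were seen. The probes that share a profile were also found in these data. Only the rules for testing them and the splits for ontology terms were written before those tests. Genes of ribosome production and protein synthesis were lower in the mutants by a small amount. Of 214 genes of the nucleolus, 154 had negative differences (median -0.12, limma camera, adjusted p = 2.65e-05, 4.36e-05 with litter as a block and 0.828 with an estimated correlation), with medians of -0.13, -0.13 and -0.11 in mutants 1, 2 and 3. The nucleolar GTPase gene Gnl3 (-0.69, SE 0.08) and Polr1b, a subunit of RNA polymerase I (-0.60, SE 0.07), were both chosen after their values were seen. Of 26 genes of aminoacyl-tRNA ligases, 26 were negative (median -0.20, adjusted p = 3.75e-05), as were 34 of 42 genes of rRNA processing (-0.19), 26 of 30 of tRNA processing (-0.23), 93 of 115 of translation (-0.11) and 54 of 65 of DNA replication (-0.12, adjusted p = 0.00145). Each of these terms also had an adjusted p of 0.828 with an estimated correlation. Mycn, a transcription factor that drives growth, was at 2.28, 1.95 and 1.95 in mutants 1, 2 and 3 and between 3.15 and 3.37 in the controls.

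Genes of homophilic cell adhesion, largely cadherins and protocadherins, were higher (41 genes, 5 of them negative, median 0.20, adjusted p = 0.000715, 0.00281 with litter as a block and 0.828 with an estimated correlation), with medians of 0.04, 0.28 and 0.33 in mutants 1, 2 and 3. Genes of the postsynaptic membrane behaved alike (51 genes, median 0.18, adjusted p = 0.00555, and 0.828 with an estimated correlation), with medians of 0.05, 0.28 and 0.33. In all 47 of 571 terms passed with the preset correlation. Of the 10 splits of the 6 arrays, 2 gave at least as many terms, with 60 in the highest other one, which sets controls 1 and 3 and mutant 3 against the rest. With 10 splits no share under 0.05 can be reached.

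A set of 183 probes, 120 of them named for 115 unrelated genes such as Mcidas, Snap25, Lhx6, Itgam and Smo, shared a profile over the arrays (-1.05, -0.10 and -0.47 in controls 1, 2 and 3, 0.16, 1.34 and 0.14 in mutants 1, 2 and 3). They were chosen from these data, by a correlation above 0.97 with the Mcidas probe and a standard deviation above 0.4 on the log2 scale. Their median correlation of 0.976 between pairs, against at most 0.133 in 100 random draws, therefore restates that choice. For 39 of these genes, 51 other probes had a median difference of 0.192 (SE 0.079), against 1.096 for the set. This argues against a response of those genes to the mutation as the source of the profile. Another probe that followed the profile would itself have joined the set, which lowers this value. The 120 named probes stand for 115 genes, so that few did. A defect at one place is argued against too, since the median distance to the nearest other such spot was 7 spots, above the lowest of 1000 random draws (5.831). The other probes correlated with the profile at a median of 0.231, a value lowered by the same choice. Probes that also bind one shared RNA may give this, and whether that RNA itself differs with the genotype stays open. Without these probes 8 genes changed, including all 7.

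Control 3 was low in subpallial genes, 18 of 20 being lowest of the controls there. That the mutation raises these genes is argued against as the whole cause of the shift of 1.32. Within litters the median difference was 0.054 (SE over genes 0.113), -0.123 (SE 0.256) and 3.898 (SE 0.441) in litters 1, 2 and 3, so that the shift lies in the litter of control 3 alone, and the median over litters was 0.054. Each litter holds 1 control and 1 mutant. The SE counts genes that vary together (estimated correlation 0.774), so it does not measure the spread between embryos. A rise hidden by such spread in litters 1 and 2 is not excluded, and the rule for this test was written after control 3 was seen to be low. Less subpallial tissue in the piece taken from that embryo could give this, but the count of 18 restates what was first seen. The amount of tissue, another stage of the embryo, a difference between embryos and a smaller effect of the mutation stay open.

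Mutant 3 was lowest of the mutants for 13 of 13 hem genes, and also in the list of the meninges and head mesenchyme (0.83, -0.22 and -0.65 in mutants 1, 2 and 3). Less cortical hem in that piece could give this, and more hem in the pieces of mutants 1 and 2 could raise hem genes there. Without mutant 3 the median difference of the hem genes other than Rspo2 and Bmp6 was 0.917, but the pair were picked as the highest of the list and were above background on 1 of the 3 control arrays each, so that the gap decides nothing. Folr1, a folate receptor of the choroid plexus list chosen after its values were seen, was also high in these embryos (-1.82, -2.12 and -5.71 in mutants 1, 2 and 3, and -4.93, -5.03 and -4.12 in controls 1, 2 and 3). The amount of hem and a response of these genes to the mutation cannot be told apart from these values.

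Of the 10 splits of the 6 arrays, only the real 1 gave as many changed genes (7, the highest other 1; 143 against 1 with trend and robust variance), and a share under 0.05 cannot be reached. Among the 4 splits that part all 3 litters, the other ones gave 0, 1 and 0. For lists, 3 of the 10 splits gave as many past the threshold as the real one (12, the highest other 12), and of the splits that part all litters the other ones gave 12, 4 and 12. Those with 12 exchange control and mutant of litter 3 or of litter 1, which is also slide 1, and with litter as a block 10 lists passed in the real split. The counts at an unadjusted p under 0.05 were 3569 for the real split and from 235 to 1282 for the others.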
